A study of Homo sapiens with 15 samples.

How the data were processed

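The study sequenced RNA ends of U2OS cells by SLAM-seq, in which 4-thiouridine in new RNA is alkylated and read as a T-to-C conversion. There were 15 libraries in 5 groups of 3: G1, Early_S, Late_S, G2 and No_alkylation. Per the labels, cells took up 4-thiouridine and EdU for 45 minutes, were fixed with glyoxal, sorted by EdU and DNA content, and gave 500 ng of RNA for 3' end libraries made with a QuantSeq kit.

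The authors mapped reads to hg38 and, per the file headers, counted reads, T>C reads and multimapped reads with slamdunk 0.2.4. Each of the 15 deposited tables lists 68625 regions near transcript ends (median 148 bases) from a merged Ensembl release 90 annotation. The read count, T>C read count, count of covered T positions and count of converted T positions were used as deposited, with no rounding or scaling. The conversion rate, a fraction of covered T positions, was made by the authors from the same columns and was recomputed here from the summed counts. The deposited CPM values were scaled by the authors to a library total that also holds reads outside the regions, of which 58.9% to 69.7% lay in the regions. These CPM values were used only for that total, and CPM in the text means normalised counts computed here. Multimapped reads were 10.9% to 12.1% of reads. Reads carried no molecular identifiers, so intervals and floors cover counting error only. The aligner settings, the fewest conversions that make a T>C read and the variant filter are not given in the sources used here.

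Regions were summed by the gene name in the files, giving 19531 names, of which 17926 are current symbols and 761 older ones; 481 names join several genes and hold 2.17% of reads. Coordinates are those of the gene's region with the most reads, counted from 1. The mitochondrial and nuclear noncoding lists had 0 genes in the files, and the list of blood cell markers had 2 measured genes, too few for a list test (0 of them called).

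Groups, comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Steady-state counts (all reads) and nascent counts (T>C reads) were each fitted over the 12 alkylated libraries by edgeR 4.0.16 quasi-likelihood (R 4.3.3), with TMM factors and filterByExpr (count minimum 10, total minimum 15). An F-test across the 4 phases and 4 contrasts of neighbouring phases (Early_S against G1, Late_S against Early_S, G2 against Late_S, G1 against G2) were adjusted by Benjamini-Hochberg within each, two-sided, and called at 0.05. The labelled share was fitted in 1 edgeR model with T>C and other reads of each library as separate columns, asking whether their ratio differed, each kind scaled by its own TMM factors. Alkylated and No_alkylation libraries were compared by a like model over 15 libraries, scaled by total reads without TMM, for genes with at least 10 reads on average and 10 T>C reads in total. Steady-state levels of No_alkylation were set against the mean of the 4 phases over all 15 libraries. Conversion rates were compared by exact permutation tests. Errors are SD over 3 libraries for levels and SE for log2 changes. This SE was computed as the size of the log2 change over the square root of its edgeR F statistic. A gene with 0 reads in a group is given a lower bound on its fold against a floor of 3 counts over the group.

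Each fixed list was tested by camera in limma 3.58.1 on log-CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 96 tests of a layer. Of these, 49 steady-state and 36 nascent tests passed, 32 and 26 with an estimated correlation; wherever a list lost its call that way the text gives that value. The fry test, which asks whether the genes of a list move on balance 1 way, called 68 and 56 tests, and in either direction 84 and 83. A list's median, mean and camera direction differed in sign in 13 steady-state tests (1 of them called, ribosomal proteins in Early_S against G1) and 15 nascent tests (0 called). Placing members with 0 reads at their bound moved no called list's median.

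The genes named are, in each contrast and layer, up to 6 each way with the largest change, at least 20 counts on average in the higher phase and no overlap between the libraries of both phases, up to 4 members of each list with the smallest p, and 17 genes fixed by name. Rule-named genes whose call ended when 1 library was left out were not described singly, except in G2 against Late_S and where stated. Genes named in the text had 135 steady-state and 75 nascent contrast calls, not all of them printed. In 133 and 75 of these, all 3 libraries of a phase lay above or below all 3 of the other. The steady-state calls of PLK1 (Early_S against G1) and CDC6 (G1 against G2) did not separate in this way. For genes not fixed by name, the rule asked for no overlap or took the smallest p, so this separation was largely set by the choice of genes. 1 further gene met the rule and is not reported here.

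Alternatives were RLE size factors, DESeq2 1.42.0, no filter, at least 50 counts on average, robust edgeR fits, the region with most reads per gene, genes with at most 10% multimapped reads, only the compared phases in the fit, the replicate number as a block, and each library left out. For T>C reads they were scaling by all reads, subtraction of the No_alkylation share, genes at 2 times background, and converted T positions as the count. For rates they were medians over genes and leaving out the 100 regions highest in No_alkylation. Alternatives chosen after seeing the data were T>C reads thinned to equal totals, leaving out Early_S 2 and G2 2 together, and list tests after background subtraction. On simulated data drawn from negative binomial distributions with the means, library sizes and dispersions of the real genes, with 100 genes changed at each size, 51% to 68% of 2-fold and 27% to 30% of 1.5-fold steady-state changes were called, against 13% to 18% and 0% to 4% for nascent levels and, for the labelled share in Late_S against Early_S, 4% and 2%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.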

Results

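Polyadenylated RNA was sequenced from U2OS cells, a human osteosarcoma line, after a pulse of metabolic RNA labelling and sorting by cell cycle phase. Growing cells took up 4-thiouridine, a uridine analogue built into RNA as it is made, together with EdU, a thymidine analogue built into replicating DNA, for 45 minutes. Fixed cells were sorted by EdU and DNA content into gates named G1, Early_S, Late_S and G2, the last of which the labels also write as G2/M. The series title calls the cells synchronised, whereas the protocol describes sorting of cells that were not synchronised. Alkylation makes 4-thiouridine read as C in place of T, so a read with such a conversion, here a T>C read, marks RNA made during the pulse. Each phase has 3 libraries, and 3 more libraries, named No_alkylation, skipped the chemical step. The labels do not say which cells the No_alkylation libraries hold, nor whether the 3 libraries of a phase come from separate cultures. The p-values for single genes and for rates below therefore measure the spread between these libraries. The camera p-values compare the genes of a list with other genes under a preset correlation between genes, so they do not rest on that spread alone. With an estimated correlation, 27 of 85 called lists lost the call. The 15 libraries held 16096695 (Early_S 3) to 21803972 (G2 3) reads in the annotated regions near transcript ends. The 12 alkylated libraries held 1812606 to 4037464 T>C reads each, and the No_alkylation libraries 175212 to 182253. All reads of a gene are called its steady-state level, its T>C reads its nascent level, and the percentage of its reads that are T>C reads its labelled share.

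Reads with a T>C conversion made up a larger part of all reads in G1 and Early_S than in Late_S and G2. T>C reads were 22.3% ± 0.740 (SD, n = 3) of reads in G1 and 18.4% ± 0.516 in Early_S, against 10.0% ± 0.0870 in Late_S and 10.1% ± 0.336 in G2. In the No_alkylation libraries, the background, they were 1.01% ± 0.0179 (n = 3). The median gene had a labelled share of 25.7% in G1, 19.8% in Early_S, 9.56% in Late_S, 9.41% in G2 and 0.409% in No_alkylation. EGR1, an early growth response factor, had a labelled share of 75.1% ± 5.24 (SD, n = 3) in G1 and 34.7% ± 2.56 in Late_S, and JUN, a subunit of the AP-1 transcription factor, one of 86.0% ± 0.571 and 87.3% ± 1.80; both were chosen after their values were seen.

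Across phases the conversion rate, the percentage of covered T positions read as C, was 2.52% ± 0.120 (SD, n = 3) in G1, 2.35% ± 0.0902 in Early_S, 1.29% ± 0.00751 in Late_S and 1.28% ± 0.0521 in G2. It differed between phases (exact permutation test over 369600 assignments, two-sided, p = 0.00117), as did the T>C read share (exact permutation p = 0.000455). Over the 12 alkylated libraries the rate was 1.86% against 0.0447% in No_alkylation (exact permutation p = 0.0022, the smallest that 455 assignments allow). Of 12909 genes tested against the No_alkylation libraries, 10901 had a labelled share above background and 0 below in edgeR. A small set carried conversions without alkylation: 276 of 11536 genes with enough reads had over 5% T>C reads in No_alkylation, UBXN6 (67.7%). TAF6 (53.6%) and LIG1 (50.8%) were among them, chosen after their values were seen. These 276 genes held 28.6% of the T>C reads in No_alkylation and 3.33% in the alkylated libraries.

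**Figure D1:**
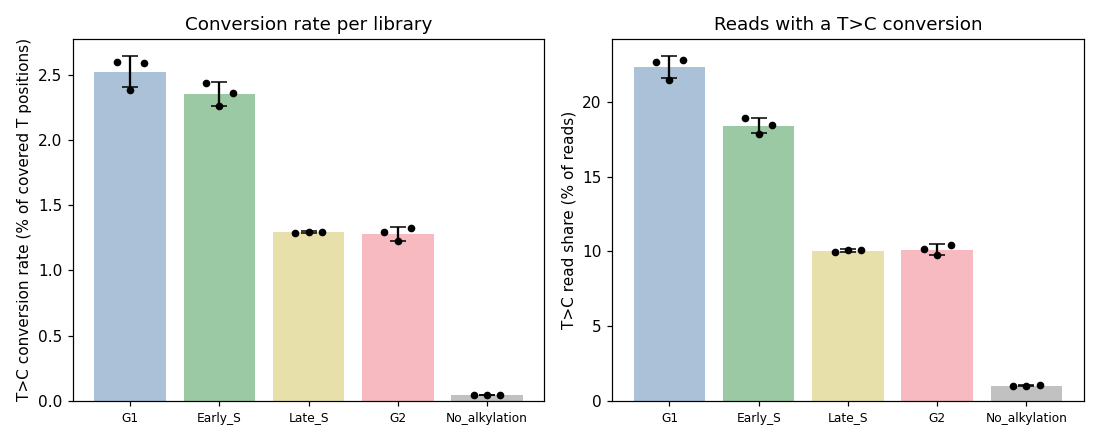
Conversion rate (left, % of covered T positions) and share of reads with a T>C conversion (right, % of reads) in each library (points), with the mean (bars) and SD of 3 libraries. Late_S and G2 lie near 1.29% and 10.0%, below every G1 and Early_S library, and No_alkylation lies at 0.0447% and 1.01%.

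The first question was which genes differ in level anywhere across the 4 phases. CCNE1, the cyclin that drives entry into S phase (hg38, chromosome 19, 29823778 to 29824308), had a steady-state level of 174 ± 8.13 CPM (normalised counts per sequencing depth, mean ± SD, n = 3) in G1, 141 ± 5.59 in Early_S, 130 ± 2.91 in Late_S and 116 ± 12.8 in G2 (adjusted p = 5.73e-05). CCNB1, the mitotic cyclin (chromosome 5, 69177524 to 69178245), went from 131 ± 17.3 through 221 ± 15.9 and 259 ± 18.3 to 345 ± 9.38 (adjusted p = 6.06e-15), and its nascent level from 175 ± 36.1 in G1 to 1084 ± 43.8 in G2 (adjusted p = 1.52e-12). PLK1, a mitotic kinase (chromosome 16, 23690064 to 23690367), went from 60.5 ± 9.51 in G1 to 242 ± 25.4 in G2 (adjusted p = 2.73e-18). CDKN1A, the p21 inhibitor of cyclin-dependent kinases (chromosome 6, 36685801 to 36687339), ran the other way, from 682 ± 37.2 in G1 through 430 ± 15.8 and 190 ± 17.9 to 149 ± 16.3 in G2 (adjusted p = 2.87e-24).

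Other cell cycle genes fixed by name gave the following. CCNA2, the S and G2 cyclin, stood at 49.3 ± 2.29 CPM (SD, n = 3) in G1 and 147 ± 13.4 in G2 (adjusted p = 9.92e-15). TOP2A, a DNA topoisomerase, stood at 35.2 ± 8.87 and 207 ± 17.9 (adjusted p = 6.26e-19). CDC20, an activator of the anaphase-promoting complex, was lowest in Early_S (224 ± 8.87) and highest in G2 (543 ± 31.6, adjusted p = 2.69e-16), with 24% of its reads mapping to more than 1 place. PCNA, the replication clamp, was highest in G1 (237 ± 13.1) and stood at 124 ± 19.0, 121 ± 11.8 and 131 ± 5.29 in the later phases (adjusted p = 5.28e-11). CDC6, an origin licensing factor, was also highest in G1, at 53.3 ± 8.07 against 27.4 ± 1.22 in Early_S (adjusted p = 0.00035). RRM2, a subunit of ribonucleotide reductase, was highest in Early_S, at 522 ± 3.97 (adjusted p = 0.0004). CCNE2 stood at 12.3 ± 1.81 in G1 and 5.10 ± 3.36 in G2 (adjusted p = 0.00188). CCND1, the G1 cyclin, ranged from 327 ± 15.2 in Early_S to 406 ± 9.25 in G1 (adjusted p = 0.00387). EGR1 fell from 102 ± 9.59 in G1 to 12.9 ± 3.21 in G2 (adjusted p = 8.76e-20) and MYC, a growth-promoting transcription factor, from 63.1 ± 9.48 to 21.1 ± 3.87 (adjusted p = 3e-10). FOS, at 5.28 ± 2.19 in G1 and 2.30 ± 0.870 in G2, did not pass (adjusted p = 0.0595). The control genes also differed: GAPDH was highest in Early_S, at 9151 ± 478 against 7382 ± 588 in G1 (adjusted p = 1.19e-07), and ACTB likewise, at 4332 ± 192 against 3746 ± 154 (adjusted p = 0.000163), with 78% of ACTB reads mapping to more than 1 place.

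**Figure D2:**
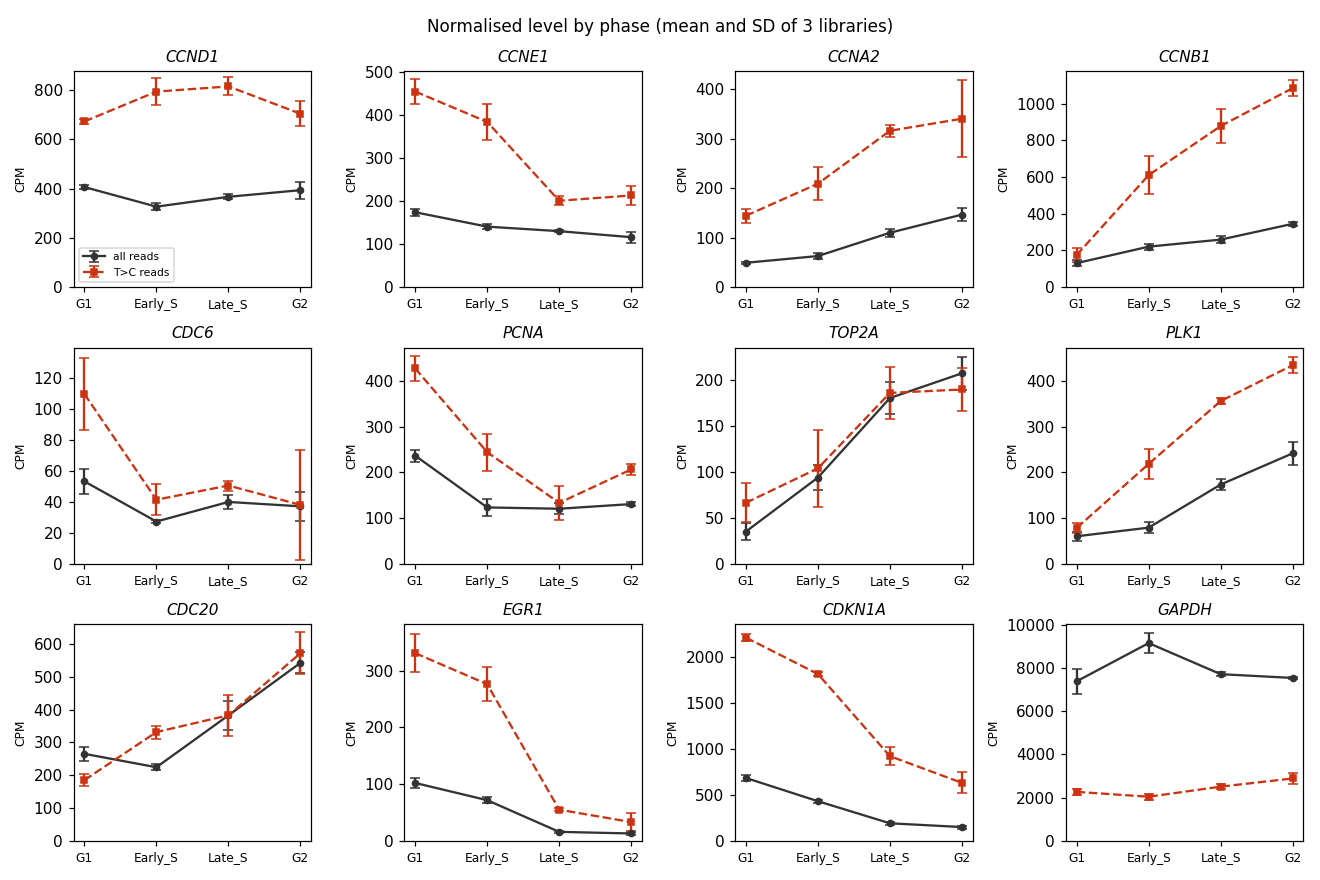
Normalised level (CPM, y axis from 0) of 12 of the genes fixed by name in each phase, for all reads and for T>C reads, as mean and SD of 3 libraries. CCNB1 and PLK1 are highest in G2, CDKN1A and EGR1 in G1.

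Of 13755 genes tested by edgeR, 4693 changed in steady-state level across phases, with 1625 of them highest in G1, 1365 in Early_S, 548 in Late_S and 1155 in G2. Of 11474 genes tested by T>C reads, 1192 changed, with 283 highest in G1, 373 in Early_S, 211 in Late_S and 325 in G2. In a principal component analysis of steady-state levels the first axis (19.8% of the variance) parted G1 from the other phases. On T>C reads the library G2 2 lay apart from the other G2 libraries (first axis 95.4 against 48.3 for G2 1). Nascent counts depend on scaling. TMM, as used here, compares a gene with the bulk of T>C reads in its library, whereas scaling by all reads keeps the lower labelling of Late_S and G2 in the values. Scaled by all reads, 6440 nascent genes changed across phases, and the median gene moved by -0.33 log2 from G1 to Early_S, -0.91 from Early_S to Late_S, -0.03 from Late_S to G2 and 1.27 from G2 to G1. Nascent changes are given relative to that bulk, and groups or genes whose direction turns with the scaling are named with both values.

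**Figure D3:**
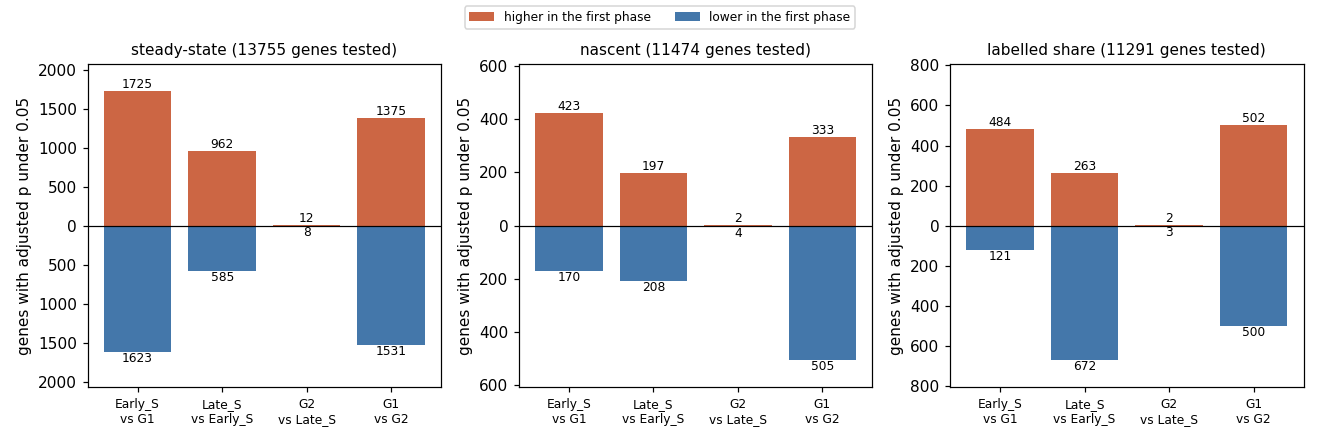
Number of genes with an adjusted p under 0.05 in each comparison of neighbouring phases (y axis; higher in the first phase upward, lower downward) for steady-state levels, nascent levels and labelled share. G2 against Late_S gave 20, 6 and 5 genes, the fewest in each panel.

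Entry into S phase was asked about by Early_S against G1. Genes of mitosis already rose between these gates, while polyadenylated histone messages and p53 target and ribosome assembly genes fell. CCNB1 rose by 0.75 ± 0.09 log2 (SE, n = 3 per phase, adjusted p = 1.73e-08) at steady state and by 1.80 ± 0.14 in T>C reads (611 ± 105 against 175 ± 36.1 CPM, adjusted p = 9.22e-10). Of 33 G2/M regulators, which include mitotic cyclins and kinases, 26 rose, 3 fell and 4 were not called (26 and 3 adjusted over the list alone, median log2 0.60, camera adjusted p = 2.08e-10). CKS1B (0.98 ± 0.08; 68% of its reads map to more than 1 place), PIMREG (1.72 ± 0.14) and AURKB (1.06 ± 0.10) were among them. Of 31 spindle, kinesin and cytokinesis genes, 22 rose and 9 were not called (25 adjusted over the list alone, median 0.68, adjusted p = 2.25e-12), with NUSAP1 (207 ± 13.2 against 93.0 ± 10.4 CPM) and TPX2 (251 ± 14.8 against 148 ± 12.5), both spindle proteins. Of 27 kinetochore and checkpoint genes, 14 rose and 13 were not called (16 up and 1 down adjusted over the list alone, median 0.51, adjusted p = 0.000138), among them SPC25 (1.96 ± 0.16; 29% multimapped) and ZWINT (0.84 ± 0.09).

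Of 28 E2F targets of the G1/S step, 3 rose, 13 fell and 12 were not called (3 and 17 adjusted over the list alone, median -0.38, adjusted p = 0.00164). UNG, which removes uracil from DNA, went to 98.6 ± 5.06 from 174 ± 11.5 CPM, and ATAD2, with 14% T>C reads in No_alkylation, to 172 ± 8.16 from 284 ± 7.96, while SKP2, a ubiquitin ligase subunit, rose to 140 ± 7.32 from 86.7 ± 13.7. Of 22 origin licensing and firing genes 2 rose, 10 fell and 10 were not called (2 and 11 adjusted over the list alone, median -0.28, adjusted p = 0.0256, but adjusted p = 0.0637 with an estimated correlation), MCM5 (-0.56 ± 0.09), CDT1 (-0.50 ± 0.09), CDC6 (-0.96 ± 0.18) and ORC6 (-0.76 ± 0.14) among those that fell. Replication fork and nucleotide genes rose, 13 up, 2 down and 14 not called of 29 (14 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.00582), with RRM1 (0.68 ± 0.07), TYMS (0.49 ± 0.06) and PRIM1 (0.91 ± 0.15) up and PCNA down (-0.94 ± 0.10). Of 26 histone genes, 1 rose, 12 fell and 13 were not called (1 and 14 adjusted over the list alone, median -1.67, adjusted p = 3.62e-09). HIST2H2BE (chromosome 1, 149884459 to 149886259) fell from 198 ± 9.69 to 23.4 ± 1.57 CPM (edgeR adjusted p = 1.19e-19), with HIST1H2BJ (-2.05 ± 0.10) and HIST1H2BD (-1.63 ± 0.17). Messages of this family can carry poly(A) tails, which this 3' end assay captures. Histone messages without such tails are not its target, so histone values here and below need not stand for all histone RNA.

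Stress and growth genes moved as well. Of 21 unfolded protein and ATF4 response genes, 11 rose, 2 fell and 8 were not called (11 and 3 adjusted over the list alone, median 0.40, adjusted p = 3.81e-05). PSAT1, a serine synthesis enzyme (chromosome 9, 78329087 to 78330093; 13% multimapped), stood at 167 ± 12.4 against 28.4 ± 4.11 CPM (log2 2.55 ± 0.12, adjusted p = 9.1e-20), SLC7A11, a cystine transporter, at 82.7 ± 3.32 against 18.1 ± 1.73, ATF4 at 711 ± 74.1 against 284 ± 49.9, and MTHFD2 at 631 ± 38.3 against 263 ± 15.5. Of 24 p53 targets, 14 fell and 10 were not called (14 adjusted over the list alone, median -0.66, adjusted p = 4.96e-06). CDKN1A (-0.67 ± 0.08), TIGAR (-1.01 ± 0.14), GADD45A (-0.86 ± 0.12) and MDM2 (-0.85 ± 0.13) were among them. Of 28 ribosome biogenesis genes, 22 fell and 6 were not called (23 adjusted over the list alone, median -0.54, adjusted p = 2.73e-11), with RRP1B (58.4 ± 8.61 against 144 ± 3.90 CPM), NCL (-0.62 ± 0.06) and NOP2 (-0.97 ± 0.11). Of 28 immediate early genes 2 rose, 14 fell and 12 were not called (2 and 15 adjusted over the list alone, median -0.45, adjusted p = 0.000435, but adjusted p = 0.0648 with an estimated correlation). JUN (-1.03 ± 0.10), CYR61 (-1.07 ± 0.10) and IER2 (-1.19 ± 0.11; 55% multimapped) fell and NR4A1, an orphan nuclear receptor, rose by 1.45 ± 0.25. Of 28 splicing factors 2 rose, 14 fell and 12 were not called (2 and 15 adjusted over the list alone, median -0.28, adjusted p = 0.000423). SRSF1 (-0.81 ± 0.08) and HNRNPU (-0.47 ± 0.06) were among them.

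Smaller shifts had a call that an estimated correlation or a single library ended. Of 25 oxidative phosphorylation genes 8 rose and 17 were not called (8 adjusted over the list alone, median 0.16, adjusted p = 0.0116, but adjusted p = 0.17 with an estimated correlation). Of 83 ribosomal protein genes 28 rose, 2 fell and 53 were not called (31 and 2 adjusted over the list alone, median 0.10, mean -0.01, camera upward, adjusted p = 0.00373, but adjusted p = 0.515 with an estimated correlation). The rise was not called without Early_S 1 or G1 2 (adjusted p up to 0.175). Of 12 apoptosis genes 2 rose, 5 fell and 5 were not called (2 and 6 adjusted over the list alone, median -0.39, adjusted p = 0.043, but adjusted p = 0.182 with an estimated correlation). The call ended in 7 of 12 fits that left out 1 library (G1 1 or 2, Early_S 1 or 2, or any Late_S library), with an adjusted p up to 0.09 without Early_S 2. Lists with no call at steady state were homologous recombination (2 up, 2 down of 18), condensin and cohesin (3 and 3 of 17), G1 and quiescence (6 and 7 of 25), heat shock (5 and 5 of 14), NF-kB and interferon (4 and 1 of 17), cholesterol synthesis (2 and 5 of 19), glycolysis and hypoxia (9 and 4 of 21), extracellular matrix (4 and 7 of 21) and epithelial markers (0 and 1 of 6).

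The genes with the largest changes here were mostly rare messages. SLITRK6, a neuronal membrane protein (chromosome 13, 85792790 to 85793982), had 821 reads in G1 and 0 in Early_S, at least 275-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 6.16e-10), and at least 191-fold lower in T>C reads (adjusted p = 8.13e-06). RPL3L, a muscle form of a ribosomal protein, CSF3, a cytokine, and LAMA4, a laminin chain, had 0 reads in Early_S as well and were at least 99.5-fold, 46.8-fold and 28.9-fold lower. ITGAM, an integrin of white blood cells (chromosome 16, 31331708 to 31332892), had 143 reads in Early_S and 1 in G1, a ratio with a counting interval of 25.1 to 5.66e+03. At steady state 3348 of 13755 genes passed, 1725 up and 1623 down, and 37.6% of genes had all 3 libraries of one phase above the 3 of the other, against 10% by chance.

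Nascent levels in Early_S against G1 gave the mitotic groups again. Of 33 G2/M regulators, 23 rose and 10 were not called (27 adjusted over the list alone, median 1.21, 0.90 scaled by all reads, camera adjusted p = 3.73e-25), among them BIRC5 (1.45 ± 0.14), CKS2 (1.24 ± 0.13; 12% multimapped), PIMREG (2.58 ± 0.24) and PLK1 (1.48 ± 0.16). Of 31 spindle and kinesin genes 19 rose and 12 were not called (27 adjusted over the list alone, median 1.06, 0.74 scaled by all reads, adjusted p = 1.13e-24), with KIF20A, a mitotic kinesin, at 91.7 ± 9.17 against 14.8 ± 3.57 CPM, KPNA2 (1.27 ± 0.08; 30% multimapped) and NUSAP1 (1.49 ± 0.14). Of 27 kinetochore genes 4 rose and 23 were not called (6 adjusted over the list alone, median 0.38, 0.07 scaled by all reads, adjusted p = 0.0131). Of 21 ATF4 response genes 12 rose, 1 fell and 8 were not called (13 and 1 adjusted over the list alone, median 0.77, adjusted p = 1.88e-09), with MTHFD2 (1.18 ± 0.12), XBP1 (1.37 ± 0.16), ATF4 (0.88 ± 0.11) and CHAC1 (2.95 ± 0.46). Of 14 heat shock genes 7 rose, 1 fell and 6 were not called (7 and 1 adjusted over the list alone, median 0.36, 0.05 scaled by all reads, adjusted p = 0.00385). HSPA1A (0.90 ± 0.11) and HSPB1 (0.88 ± 0.11) were among them.

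Falling groups in T>C reads were histones, replication licensing and p53 targets. Of 21 histone genes 1 rose, 9 fell and 11 were not called (1 and 10 adjusted over the list alone, median -1.65, adjusted p = 1.88e-09). HIST2H2BE stood at 46.8 ± 3.44 against 462 ± 17.5 CPM and HIST1H2AG at 6.18 ± 2.41 against 67.3 ± 9.40, while HIST1H4C, the 1 that rose, stood at 1293 ± 388 against 453 ± 75.5. Of 22 origin licensing genes 1 rose, 5 fell and 16 were not called (1 and 9 adjusted over the list alone, median -0.75, adjusted p = 0.000109). MCM2 fell by 1.10 ± 0.20 log2. Of 28 E2F targets 3 fell and 25 were not called (3 adjusted over the list alone, median -0.34, adjusted p = 0.000109). Of 24 p53 targets 5 fell and 19 were not called (8 adjusted over the list alone, median -0.66, adjusted p = 6.3e-06). CYR61 fell by 1.03 ± 0.12 and NR4A1 rose by 2.41 ± 0.39 in an immediate early list that was not called (2 up, 3 down of 26, adjusted p = 0.0752). Matrix genes rose, 4 up, 1 down and 14 not called of 19 (6 and 4 adjusted over the list alone, median 0.42, 0.12 scaled by all reads, adjusted p = 0.024, but adjusted p = 0.0626 with an estimated correlation). TIMP1, a metalloproteinase inhibitor (919 ± 64.2 against 169 ± 17.8 CPM), COL1A1 (3906 ± 88.0 against 1856 ± 18.5; 9.6% T>C reads in No_alkylation) and TAGLN (181 ± 26.0 against 34.4 ± 9.57) were among them, and the call ended without G1 1 or Early_S 2 (adjusted p up to 0.0536). KRT8, a keratin of the epithelial list (2 up adjusted over the list alone, 1 over all genes, of 5, adjusted p = 0.779; 55% multimapped), stood at 781 ± 6.45 against 383 ± 13.4.

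2 further nascent lists of this comparison had calls that did not last. Replication fork genes fell, 3 down and 26 not called of 29 (4 adjusted over the list alone, median -0.28, adjusted p = 0.024, but adjusted p = 0.108 with an estimated correlation). It was lost without Early_S 1, Early_S 3 or G1 2 (adjusted p up to 0.0995). Ribosome biogenesis genes fell, 2 down and 26 not called of 28 (2 adjusted over the list alone, median -0.21, adjusted p = 0.0238, but adjusted p = 0.0554 with an estimated correlation). That call did not survive leaving out Early_S 1 or G1 2 (adjusted p up to 0.101). ARNTL, a circadian clock factor, had 88 T>C reads in Early_S and 0 in G1, at least 35.7-fold higher (edgeR adjusted p = 0.00126). Over all genes 593 of 11474 passed, 423 up and 170 down, and 25.8% of genes had non-overlapping libraries against 10% by chance. Scaled by all reads 832 passed, 205 up and 627 down. The count was 358 without G1 3, 369 without G1 1 and 389 without Early_S 2. Of the 593 nascent calls, 284 rises and 150 falls were also called at steady state. Independent layers would share 61.5 and 23.6, but these layers are not independent, because T>C reads are part of all reads. In the opposite direction, 19 nascent rises were steady-state falls and 5 nascent falls were steady-state rises.

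Progress through S phase was asked about by Late_S against Early_S. Mitotic genes rose further, condensin and cohesin and ribosome biogenesis genes rose, and immediate early, p53 target and matrix genes fell. AURKA, a mitotic kinase (chromosome 20, 56369389 to 56370469), rose from 74.1 ± 6.18 to 185 ± 20.2 CPM (SD, n = 3; log2 1.32 ± 0.11 SE, adjusted p = 3.26e-11). Of 33 G2/M regulators 14 rose, 1 fell and 18 were not called (22 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 1.72e-10). PLK1 (1.13 ± 0.11), TOP2A (0.94 ± 0.12), CCNA2 (0.81 ± 0.11) and CDC20 (0.77 ± 0.08) were among them. Of 31 spindle and kinesin genes 16 rose and 15 were not called (23 adjusted over the list alone, median 0.54, adjusted p = 3.24e-14), with KIF23 (172 ± 11.7 against 97.1 ± 2.63 CPM) and KPNA2 (800 ± 18.7 against 556 ± 28.9). Of 27 kinetochore genes 13 rose, 1 fell and 13 were not called (13 and 1 adjusted over the list alone, median 0.40, adjusted p = 4.77e-07). CENPF (1.10 ± 0.12) and BUB1B (1.35 ± 0.18) were among them. Condensin and cohesin genes rose, 8 of 17 with 9 not called (11 adjusted over the list alone, median 0.39, adjusted p = 2.97e-06). SMC4 (0.74 ± 0.08) and WAPL (1.08 ± 0.15) were among them. Of 28 ribosome biogenesis genes 14 rose and 14 were not called (19 up and 1 down adjusted over the list alone, median 0.43, adjusted p = 2.08e-10). RRP1B at 132 ± 12.5 against 58.4 ± 8.61 CPM and NOP16 (0.79 ± 0.11) were among them.

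Immediate early genes fell together in Late_S, 14 down, 1 up and 13 not called of 28 (18 and 1 adjusted over the list alone, median -0.79, adjusted p = 2.72e-12). EGR1 (chromosome 5, 138468082 to 138469315) fell from 71.6 ± 5.72 to 15.8 ± 2.19 CPM (log2 -2.18 ± 0.16, adjusted p = 5.13e-13), IER3 from 490 ± 48.7 to 219 ± 7.20, ATF3 from 43.6 ± 1.63 to 12.2 ± 0.502, and MYC by 1.01 ± 0.18 log2. Of 24 p53 targets 6 fell and 18 were not called (12 adjusted over the list alone, median -0.40, adjusted p = 2.45e-07). CDKN1A (-1.18 ± 0.08), SESN2 (-1.11 ± 0.15) and GADD45A (-0.84 ± 0.12) were among them. Of 83 ribosomal protein genes 58 fell and 25 were not called (67 down and 1 up adjusted over the list alone, median -0.22, adjusted p = 7.59e-14, but adjusted p = 0.139 with an estimated correlation). RPS16 (-0.27 ± 0.04) and RPS14 (-0.30 ± 0.05; 23% multimapped) were among them. Of 25 oxidative phosphorylation genes 6 fell and 19 were not called (14 adjusted over the list alone, median -0.21, adjusted p = 1.07e-05). COX5B fell by 0.52 ± 0.09 log2. Of 21 ATF4 response genes 6 fell and 15 were not called (7 adjusted over the list alone, median -0.22, adjusted p = 0.000423). CHAC1 fell by 2.05 ± 0.30 log2. Of 21 matrix genes 2 rose, 6 fell and 13 were not called (2 and 10 adjusted over the list alone, median -0.26, adjusted p = 0.00348). COL1A1 fell by 0.27 ± 0.05 log2. Of 25 G1 and quiescence genes 2 rose, 6 fell and 17 were not called (2 and 7 adjusted over the list alone, median -0.26, adjusted p = 0.00977).

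Heat shock genes rose, 7 up, 3 down and 4 not called of 14 (9 and 3 adjusted over the list alone, median 0.25, adjusted p = 0.0309, but adjusted p = 0.139 with an estimated correlation). The call ended without Early_S 2 or Late_S 2 (adjusted p up to 0.0574). Splicing factors rose, 8 up, 1 down and 19 not called of 28 (9 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.0243, but adjusted p = 0.105 with an estimated correlation). It was lost without Late_S 2 (adjusted p = 0.053). Apoptosis genes fell, 4 down and 8 not called of 12 (4 adjusted over the list alone, median -0.37, adjusted p = 0.0262, but adjusted p = 0.152 with an estimated correlation). That call did not survive leaving out Early_S 3 (adjusted p = 0.224). Among 26 histone genes HIST1H4C fell by 1.26 ± 0.13 log2, but the list was not called (1 up, 2 down, adjusted p = 0.369). GAPDH fell by 0.25 ± 0.04. ESM1, a secreted proteoglycan (chromosome 5, 54977864 to 54979331), rose from 13.3 ± 1.33 to 62.9 ± 2.03 CPM (adjusted p = 4.74e-16) and ACTR5, a chromatin remodelling subunit, from 2.59 ± 1.10 to 11.4 ± 1.83. CYSRT1 had 95 reads in Early_S and 0 in Late_S, at least 35.0-fold lower, and KLHL26 fell from 3.23 ± 1.05 to 0.170 ± 0.294. At steady state 1547 of 13755 genes passed in edgeR, 962 up and 585 down, and 28.5% of genes had non-overlapping libraries against 10% by chance; without Late_S 3 the count was 947.

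T>C reads in Late_S against Early_S gave rises for mitotic genes, relative to the bulk of T>C reads. Among G2/M regulators 6 of 33 rose and 27 were not called (11 up and 1 down adjusted over the list alone, median 0.26, but -0.65 scaled by all reads, camera adjusted p = 8.4e-05). CCNF (0.67 ± 0.13, -0.24 scaled by all reads) and GTSE1 (0.99 ± 0.20, 0.09 scaled by all reads, where its call ended) were among them. Of 31 spindle and kinesin genes 5 rose and 26 were not called (12 adjusted over the list alone, median 0.48, but -0.43 scaled by all reads, adjusted p = 6.3e-06). KIF23 (0.81 ± 0.14, -0.10 scaled by all reads) and KPNA2 (0.49 ± 0.08, -0.41 scaled by all reads) were among them. Of 27 kinetochore genes 4 rose and 23 were not called (6 adjusted over the list alone, median 0.34, but -0.56 scaled by all reads, adjusted p = 0.0132). Ribosome biogenesis genes rose, 2 of 28 with 26 not called (5 adjusted over the list alone, median 0.25, but -0.64 scaled by all reads, adjusted p = 0.00837). Ribosomal protein genes rose, 9 up, 2 down and 72 not called of 83 (16 and 2 adjusted over the list alone, median 0.16, but -0.75 scaled by all reads, adjusted p = 8.9e-05, but adjusted p = 0.0877 with an estimated correlation). RPS29, with 23% T>C reads in No_alkylation, stood at 0.71 ± 0.06, at -0.20 scaled by all reads, and was no longer called once background was subtracted.

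Other groups fell in T>C reads, and scaling by all reads, which put the median gene at -0.91 log2, could only add to the fall. Of 24 p53 targets 1 rose, 4 fell and 19 were not called (1 and 7 adjusted over the list alone, median -0.38, camera adjusted p = 0.00183). CDKN1A at 919 ± 96.3 against 1811 ± 19.9 CPM and RRM2B at 57.9 ± 8.66 against 156 ± 24.9 were among them. Of 29 replication fork genes 3 fell and 26 were not called (1 up and 7 down adjusted over the list alone, median -0.42, adjusted p = 0.00372, but adjusted p = 0.0516 with an estimated correlation). RRM2 fell by 0.59 ± 0.10 log2. Of 21 ATF4 response genes 5 fell and 16 were not called (8 adjusted over the list alone, median -0.48, adjusted p = 0.00868). MTHFD2 fell by 0.62 ± 0.12 log2. Of 19 matrix genes 6 fell and 13 were not called (1 up and 7 down adjusted over the list alone, median -0.52, adjusted p = 0.000839), TIMP1 going from 919 ± 64.2 to 174 ± 17.8 CPM (log2 -2.40 ± 0.17). CCNE1 (-0.94 ± 0.15), EGR1 (-2.33 ± 0.24) and KRT8 (-1.02 ± 0.14) fell as well, while JUN rose by 0.68 ± 0.11, or stood at -0.22 scaled by all reads. Among the largest changes, GPSM2, a spindle orientation protein, rose from 6.94 ± 1.09 to 62.5 ± 9.06 CPM, and S1PR3, a lipid receptor, and SESN1, a stress sensor, fell from 36.3 ± 10.1 to 1.63 ± 1.53 and from 26.3 ± 7.35 to 2.01 ± 1.76. GCH1, an enzyme of biopterin synthesis, had 108 T>C reads in Early_S and 0 in Late_S, at least 20.6-fold lower.

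In this comparison 405 of 11474 nascent genes passed in edgeR, 197 up and 208 down, and 22.5% of genes had non-overlapping libraries against 10% by chance. Scaled by all reads 4196 passed, 11 up and 4185 down. The count was 226 without Early_S 2 and 260 without Early_S 3. With steady-state calls, 78 rises and 72 falls were shared, against 16.5 and 10.4 for independent layers. In the opposite direction, 11 nascent rises were steady-state falls and 10 nascent falls were steady-state rises.

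The step from late S phase into G2 was asked about by G2 against Late_S. In all 20 genes passed, 12 up and 8 down. KPNA2, a nuclear import factor (chromosome 17, 68046597 to 68046842; 30% multimapped), rose from 800 ± 18.7 to 1033 ± 8.93 CPM (SD, n = 3; log2 0.37 ± 0.06 SE, adjusted p = 0.00208). CDC20 rose from 383 ± 43.6 to 543 ± 31.6 (adjusted p = 0.00154), KIF2C, a microtubule-depolymerising kinesin, from 159 ± 17.4 to 238 ± 6.09, CKS2 from 143 ± 11.2 to 212 ± 9.16, PTTG1, the securin, from 271 ± 22.1 to 363 ± 14.3, and CCNB1 from 259 ± 18.3 to 345 ± 9.38 (adjusted p = 0.0346). GPT2, an alanine aminotransferase (chromosome 16, 46928998 to 46931297), fell from 139 ± 3.12 to 79.9 ± 7.50 (adjusted p = 2.84e-05) and ATF3 from 12.2 ± 0.502 to 5.47 ± 1.48 (adjusted p = 0.00388; not called with only both phases in the fit). Several calls rested on single libraries. Without Late_S 3 those of KIF2C (adjusted p = 0.0896), CDC20 (0.069), CKS2 (0.0913), PTTG1 and CCNB1 (0.256) ended; without Late_S 1 those of CKS2, PTTG1 (0.218) and CCNB1; and without G2 2 or G2 3 that of CCNB1. PLK1, at 242 ± 25.4 against 174 ± 11.1, missed the threshold (adjusted p = 0.0653, but called in DESeq2, with the replicate block and in robust fits, among others), as did CDKN1A (149 ± 16.3 against 190 ± 17.9, adjusted p = 0.068, called in the same 3 alternatives), CCNA2 (adjusted p = 0.137, but called in DESeq2) and TOP2A (adjusted p = 0.665).

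As a group, G2/M regulators rose, 5 up and 28 not called of 33 (21 up and 1 down adjusted over the list alone, median 0.40, camera adjusted p = 5.76e-15), and so did spindle and kinesin genes, 3 up and 28 not called of 31 (14 adjusted over the list alone, median 0.33, adjusted p = 3.6e-14). Smaller list shifts did not hold. Kinetochore genes rose as a group with 0 of 27 called (1 adjusted over the list alone, median 0.11, adjusted p = 0.0312, but adjusted p = 0.0648 with an estimated correlation). The call ended without Late_S 1, G2 1 or G2 3 (adjusted p up to 0.137). Replication fork genes fell with 0 of 29 called (2 down adjusted over the list alone, median -0.10, adjusted p = 0.0312, but adjusted p = 0.066 with an estimated correlation). It was lost without Late_S 2, G2 2 or G2 3 (adjusted p up to 0.208). Ribosome biogenesis genes rose with 0 of 28 called (1 adjusted over the list alone, median 0.06, adjusted p = 0.0312, but adjusted p = 0.0648 with an estimated correlation). That call did not survive leaving out G2 1, G2 3, Late_S 2 or Late_S 3 (adjusted p up to 0.104). ATF4 response genes fell, 1 of 21 down with 20 not called (4 adjusted over the list alone, median -0.14, adjusted p = 0.0129, but adjusted p = 0.0588 with an estimated correlation). The call ended without Late_S 2 (adjusted p = 0.0513). In all 20 of 13755 genes passed in edgeR, 12 up and 8 down, against 1315 at an unadjusted p under 0.05 and 115 in DESeq2; 14.8% of genes had non-overlapping libraries against 10% by chance. The count was 3 without Late_S 3, 7 without Late_S 1, 10 without G2 2 and 37 without G1 2.

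Of T>C reads 6 genes of 11474 passed, against 1158 at an unadjusted p under 0.05 and 103 in DESeq2. DUT, which removes dUTP (1.21 ± 0.22), and THBS1, a matrix glycoprotein (0.81 ± 0.13), rose; ATF3 (-2.55 ± 0.48), the keratin-associated gene KRTAP2-3 (-0.56 ± 0.09), CDKN1A (-0.55 ± 0.11) and the metallothionein MT2A fell. MT2A (chromosome 16, 56609186 to 56609497), at 2732 ± 111 against 3916 ± 117 CPM (SD, n = 3; log2 -0.52 ± 0.06, adjusted p = 1.24e-05), kept its call without any 1 library. With only the Late_S and G2 libraries in the fit 1 gene passed, and the calls of DUT, THBS1, ATF3, KRTAP2-3 and CDKN1A ended. That of CDKN1A also ended scaled by all reads (adjusted p = 0.0626), and those of CDKN1A and ATF3 with background subtracted or converted T positions as the count. Leaving out single libraries ended those of THBS1 (Late_S 1, adjusted p = 0.0934), KRTAP2-3 (Late_S 1 or G2 3, up to 0.112), DUT (7 of 12 libraries, up to 0.118), CDKN1A (9 of 12, up to 0.176) and ATF3 (10 of 12, up to 0.118). Counts without 1 library ran from 1 (Late_S 1) through 3 (G1 1, G1 2, G1 3 or Early_S 1) to 19 (G2 2). G2/M regulators rose as a group in T>C reads with 0 of 33 called (1 adjusted over the list alone, median 0.23, camera adjusted p = 0.00341), and spindle genes with 0 of 31 called (3 adjusted over the list alone, median 0.22, adjusted p = 0.0324, but adjusted p = 0.0626 with an estimated correlation). It was lost without G2 1, G2 2 or Late_S 2 (adjusted p up to 0.171). Other nascent lists were not called here.

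Exit from mitosis was asked about by G1 against G2. Mitotic genes were far lower in G1, and polyadenylated histone messages and p53 target and immediate early genes were higher. All 31 spindle and kinesin genes fell (31 adjusted over the list alone, median log2 -1.58, camera adjusted p = 6.2e-32), TPX2 from 467 ± 26.9 to 148 ± 12.5 CPM (SD, n = 3, adjusted p = 8.9e-20), KPNA2 by 1.40 ± 0.06 log2 and NEK2, a centrosome kinase, from 109 ± 4.62 to 18.8 ± 3.41. Of 33 G2/M regulators 27 fell and 6 were not called (27 adjusted over the list alone, median -1.40, adjusted p = 1.11e-24). TOP2A (chromosome 17, 40388516 to 40389518) stood at 35.2 ± 8.87 against 207 ± 17.9 CPM (log2 -2.56 ± 0.13, adjusted p = 5.22e-19). AURKA stood at 51.0 ± 10.2 against 230 ± 7.52, PLK1 at 60.5 ± 9.51 against 242 ± 25.4, CCNB1 at 131 ± 17.3 against 345 ± 9.38, and UBE2S, with 97% of its reads multimapped, at 377 ± 17.5 against 998 ± 110. Of 27 kinetochore genes 18 fell and 9 were not called (19 adjusted over the list alone, median -0.90, adjusted p = 1.3e-13). CENPF (-1.81 ± 0.12) was among them, and of 17 condensin and cohesin genes 11 fell and 6 were not called (11 adjusted over the list alone, median -0.47, adjusted p = 3.19e-05). NCAPD2 fell by 1.53 ± 0.10 log2.

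Of 26 histone genes 11 were higher in G1 and 15 were not called (15 adjusted over the list alone, median 1.72, adjusted p = 2.44e-11). HIST2H2BE stood at 198 ± 9.69 against 22.3 ± 3.84 CPM and HIST1H2BJ at 324 ± 15.4 against 73.9 ± 6.68. Of 24 p53 targets 19 rose and 5 were not called (20 adjusted over the list alone, median 1.13, adjusted p = 5.76e-15). CDKN1A (2.19 ± 0.08) and GADD45A (2.17 ± 0.12) were among them. Of 28 immediate early genes 17 rose, 1 fell and 10 were not called (18 and 1 adjusted over the list alone, median 1.25, adjusted p = 2.85e-14). EGR1 (2.98 ± 0.17), ATF3 (3.33 ± 0.21; chromosome 1, 212619106 to 212620777) and IER3 (1.69 ± 0.08) were among them. Of 12 apoptosis genes 7 rose and 5 were not called (7 adjusted over the list alone, median 1.06, adjusted p = 0.000858, but adjusted p = 0.0547 with an estimated correlation). PMAIP1 (1.69 ± 0.12) and BBC3 (2.46 ± 0.31), both inhibitors of survival proteins, were among them. Of 28 E2F targets 10 rose, 2 fell and 16 were not called (10 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.0136). UNG (0.89 ± 0.10), CCNE1 (0.58 ± 0.10) and CDC25A (0.77 ± 0.13) were among them. Of 22 origin licensing genes 8 rose, 1 fell and 13 were not called (8 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.0229, but adjusted p = 0.0588 with an estimated correlation). MCM5 (0.84 ± 0.09) and CDT1 (0.69 ± 0.09) were among them; the list call ended without G1 2 (adjusted p = 0.0501). PCNA, of the replication fork list (3 up and 8 down of 29, not called, adjusted p = 0.383), rose by 0.86 ± 0.10, and MYC by 1.58 ± 0.18.

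Ribosomal protein genes were slightly higher in G1, 36 up, 2 down and 45 not called of 83 (38 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.000435, but adjusted p = 0.44 with an estimated correlation). Matrix genes rose, 8 up, 1 down and 12 not called of 21 (8 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.00555). Splicing factors rose, 12 up, 2 down and 14 not called of 28 (14 and 3 adjusted over the list alone, median 0.20, adjusted p = 0.0243, but adjusted p = 0.105 with an estimated correlation). That call did not survive leaving out G2 1 (adjusted p = 0.063). HSPA1A (-1.31 ± 0.09) and HSPA8 (-0.69 ± 0.06; 82% multimapped) fell in a heat shock list that was not called (3 up, 5 down of 14, adjusted p = 0.481). SLITRK6 had 821 reads in G1 and 0 in G2, at least 305-fold higher, with HIST1H2BF, CCNB3, a meiotic cyclin, and XIRP2, an actin-binding muscle protein, at least 57.7-fold, 37.5-fold and 34.9-fold higher. SLC4A4, a bicarbonate transporter, had 68 reads in G2 and 0 in G1, at least 20.8-fold lower in G1, and ITGAM 160 and 1, a ratio with a counting interval of 25.4 to 5.71e+03. At steady state 2906 of 13755 genes passed in edgeR, 1375 up and 1531 down, and 35.2% of genes had non-overlapping libraries against 10% by chance. GAPDH (adjusted p = 0.678), ACTB (0.97), CCND1 (0.734) and RRM2 (0.454) did not pass.

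Nascent levels in G1 against G2 were lower for 3 mitotic lists, while condensin and cohesin genes were not called (1 up, 1 down of 17, adjusted p = 0.888). G2/M regulators fell, 27 of 33 with 6 not called (2 up and 30 down adjusted over the list alone, median -1.63, or -0.40 scaled by all reads, camera adjusted p = 3.16e-32). CCNB1 at 175 ± 36.1 against 1084 ± 43.8 CPM (SD, n = 3, adjusted p = 2.16e-13), CCNF (-2.24 ± 0.14) and PLK1 (-2.47 ± 0.17) were among them. Of 31 spindle and kinesin genes 27 fell and 4 were not called (29 adjusted over the list alone, median -1.59, or -0.37 scaled by all reads, adjusted p = 9.52e-35), KIF20A (chromosome 5, 138187414 to 138187715) at 14.8 ± 3.57 against 173 ± 52.7 and NEK2 at -2.78 ± 0.23 log2. Of 27 kinetochore genes 9 fell and 18 were not called (1 up and 11 down adjusted over the list alone, median -0.50, but 0.78 scaled by all reads, adjusted p = 3.93e-06). Heat shock genes fell, 10 of 14 with 4 not called (10 adjusted over the list alone, median -0.56, but 0.68 scaled by all reads, adjusted p = 3.93e-06). HSPA1A fell by 1.60 ± 0.12 and HSP90AA1 at -0.76 ± 0.06, or 0.49 scaled by all reads. Ribosomal protein genes fell, 30 down, 2 up and 51 not called of 83 (37 and 3 adjusted over the list alone, median -0.29, but 0.95 scaled by all reads, adjusted p = 1.88e-09). RPS29, at -0.99 ± 0.06, stood at 0.25 scaled by all reads and, not called, at 0.21 once background was subtracted. ATF4 response genes fell, 4 down, 2 up and 15 not called of 21 (6 and 2 adjusted over the list alone, median -0.41, but 0.84 scaled by all reads, adjusted p = 0.0167, but adjusted p = 0.0517 with an estimated correlation). COL1A1 fell by 0.89 ± 0.07, or stood at 0.36 scaled by all reads.

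Other nascent groups were higher in G1, and scaling by all reads, which put the median gene at 1.27 log2, could only add to this. Of 24 p53 targets 13 rose and 11 were not called (18 adjusted over the list alone, median 1.11, camera adjusted p = 5.58e-11). CDKN1A stood at 2206 ± 37.2 against 629 ± 112 CPM (SD, n = 3). Of 28 E2F targets 5 rose and 23 were not called (7 adjusted over the list alone, median 0.58, adjusted p = 0.00169). CCNE1 (1.09 ± 0.15) was among them. Of 22 origin licensing genes 6 rose, 1 fell and 15 were not called (9 and 1 adjusted over the list alone, median 0.61, adjusted p = 0.00385, but adjusted p = 0.0517 with an estimated correlation). Of 29 replication fork genes 8 rose, 1 fell and 20 were not called (8 and 1 adjusted over the list alone, median 0.57, adjusted p = 0.000823). TYMS (1.07 ± 0.13), FEN1 (0.91 ± 0.13) and PCNA (1.05 ± 0.18) were among them. Of 21 histone genes 6 rose, 1 fell and 14 were not called (7 and 1 adjusted over the list alone, median 1.32, adjusted p = 0.000269). HIST2H2BE (3.05 ± 0.34) and HIST1H2BJ (2.30 ± 0.19) were among them. Immediate early genes rose, 8 up, 1 down and 17 not called of 26 (9 and 1 adjusted over the list alone, median 0.35, adjusted p = 0.0232, but adjusted p = 0.189 with an estimated correlation). EGR1 (3.32 ± 0.25) and ATF3 (4.79 ± 0.48) were among them, and the list call ended without G1 2 or G2 3 (adjusted p up to 0.0814). Apoptosis genes rose, 4 of 12 with 8 not called (4 up and 1 down adjusted over the list alone, median 0.36, adjusted p = 0.0328, but adjusted p = 0.0867 with an estimated correlation). The call ended without G1 2, G2 1 or G2 3 (adjusted p up to 0.134).

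Among single genes, KRT75, a hair follicle keratin (chromosome 12, 52424070 to 52424516), had 944 T>C reads in G1 and 0 in G2, at least 148-fold higher (edgeR adjusted p = 4.27e-07), with SLITRK6 and RRAD, a small GTPase, at least 112-fold and 34.1-fold higher. TNFAIP8L1 (chromosome 19, 4652431 to 4655568) fell from 234 ± 43.2 CPM (SD, n = 3) in G2 to 5.16 ± 1.15 in G1 (adjusted p = 2.16e-13). GPSM2 and SAPCD2, both spindle orientation genes, fell from 97.8 ± 34.0 to 4.60 ± 4.95 and from 201 ± 44.2 to 13.3 ± 11.2, and DNMT3B, a DNA methyltransferase, from 70.8 ± 30.5 to 5.34 ± 3.87. Over all genes 838 of 11474 passed, 333 up and 505 down, and 25.7% of genes had non-overlapping libraries against 10% by chance; scaled by all reads 6198 passed, 6137 up and 61 down. The count was 542 without G1 1 and 543 without G1 3. With steady-state calls 191 rises and 235 falls were shared, against 38.8 and 65.9 for independent layers. In the opposite direction, 11 nascent rises were steady-state falls and 39 nascent falls were steady-state rises.

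**Figure D4:**
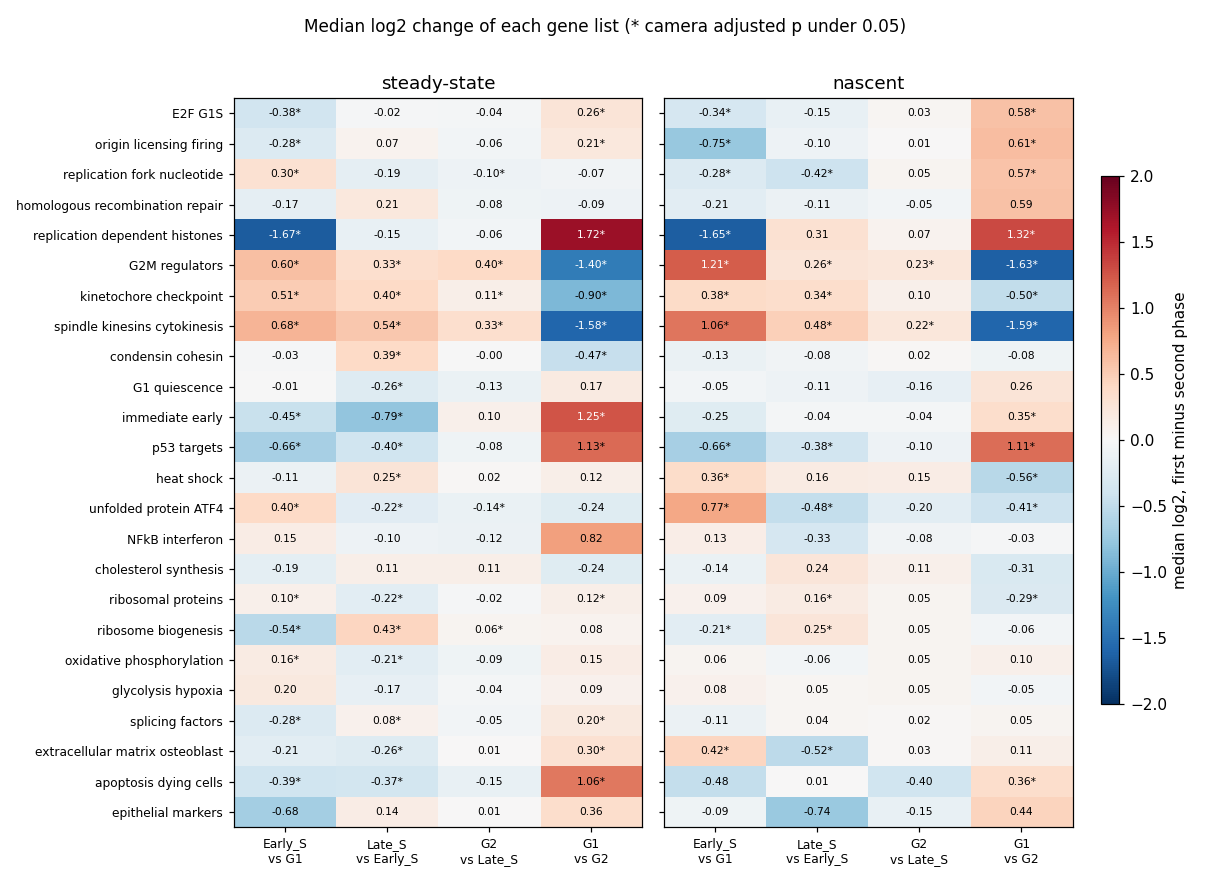
Median log2 change of each gene list with enough members (first minus second phase, colour and number) in each comparison of neighbouring phases, for steady-state and nascent levels; a star marks a camera adjusted p under 0.05. In G1 against G2 the lowest medians are those of G2/M regulators (-1.40 steady-state, -1.63 nascent) and spindle genes (-1.58 and -1.59). Nascent medians turn sign when scaled by all reads for ribosomal protein (-0.29 to 0.95), heat shock, ATF4 response and kinetochore genes in G1 against G2. They also turn sign for the called rises of mitotic, ribosomal protein and ribosome biogenesis genes in Late_S against Early_S.

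The labelled share asks whether nascent and steady-state RNA of a gene move apart, relative to the labelling of the whole library. No list test was run on shares, so lists are given as counts. In Early_S against G1 TIMP1 (chromosome X, 47586692 to 47586789) had a labelled share of 24.9% ± 0.352 (SD, n = 3) in Early_S against 3.80% ± 0.231 in G1 (log2 3.46 ± 0.17 SE, adjusted p = 1.68e-12), KIF20A one of 45.4% ± 5.24 against 7.66% ± 1.67 and CD82, a tetraspanin, one of 30.1% ± 3.52 against 4.06% ± 1.34. CYB5A, a cytochrome b5 (4.19% ± 2.22 against 28.8% ± 3.52), and UCP2, a mitochondrial carrier (2.29% ± 0.336 against 15.9% ± 4.32), fell. Of 33 G2/M regulators 14 rose, 2 fell and 17 were not called (16 and 4 adjusted over the list alone, median 0.79, or 0.38 with total reads as library size), and of 19 matrix genes 5 rose and 14 were not called (5 adjusted over the list alone, median 0.68, or 0.29). Spindle genes had 6 up and 25 not called of 31 (12 adjusted over the list alone, median 0.55, or 0.14), kinetochore genes 1 up, 1 down and 25 not called of 27 (median 0.07, but -0.32 with total reads as library size) and condensin and cohesin genes 1 up and 16 not called of 17 (median -0.14, or -0.53). Heat shock genes had 5 up, 1 down and 8 not called of 14 (5 and 1 adjusted over the list alone), with a median of 0.30, but -0.09 with total reads as library size. In Late_S against Early_S the share of ribosomal protein genes rose relative to other genes, 64 up and 19 not called of 83 (74 up and 2 down adjusted over the list alone, median 0.60), but their median was -0.55, with 67 down, with total reads as library size. Immediate early genes had 8 up, 3 down and 12 not called of 23 (8 and 4 adjusted over the list alone, median 0.48, but -0.69 with total reads as library size). Lists with more falls included spindle genes, 8 down and 23 not called of 31 (9 down adjusted over the list alone, median -0.34). G2/M regulators had 7 down and 26 not called of 33 (1 up and 9 down adjusted over the list alone, median -0.15). Matrix genes had 1 up, 6 down and 12 not called of 19 (median -0.31). Ribosome biogenesis genes had 1 up, 8 down and 19 not called of 28 (median -0.14). TIMP1 fell back to 3.12% ± 0.456 (adjusted p = 5.45e-09; chosen after its values were seen).

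In G1 against G2 the share of ribosomal protein genes was lower relative to other genes, 69 down, 1 up and 13 not called of 83 (73 and 1 adjusted over the list alone, median -0.72, but 0.86, with 74 up, with total reads as library size). Replication fork genes had 8 up, 1 down and 20 not called of 29 (10 and 1 adjusted over the list alone, median 0.75) and E2F targets 6 up and 22 not called of 28 (8 adjusted over the list alone, median 0.88). ZNF160, a zinc finger gene, had a share of 75.7% ± 10.5 (SD, n = 3) in G1 and 97.2% ± 2.48 in G2 (adjusted p = 0.00299). In G2 against Late_S 5 genes passed, against 949 at an unadjusted p under 0.05: DUT (6.54% ± 1.60 against 2.60% ± 0.333) and HIST1H4C (52.3% ± 2.09 against 37.1% ± 2.13) rose, and KRTAP2-3 (32.4% ± 4.42 against 46.3% ± 0.736), ANKRD1 (67.3% ± 0.612 against 76.8% ± 0.393) and MT2A (3.59% ± 0.180 against 4.66% ± 0.198) fell. Counted by converted T positions in place of reads, the calls of HIST1H4C, KRTAP2-3, ANKRD1 and MT2A ended, and with total reads as library size that of HIST1H4C (adjusted p = 0.0637). Without Late_S 3 the calls of DUT (adjusted p = 0.0514), HIST1H4C, ANKRD1 and MT2A (0.144) ended, without Late_S 2 those of HIST1H4C (0.146), ANKRD1 (0.0537) and MT2A, without G2 1 those of HIST1H4C and MT2A, without G2 2 that of HIST1H4C, and without Late_S 1 or G2 3 that of MT2A; the count was 1 without Late_S 3 and 2 without Late_S 2.

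Over 11291 genes the share changed across phases for 1676 in edgeR. Early_S against G1 gave 605 (484 up, 121 down), Late_S against Early_S 935 (263 up, 672 down) and G1 against G2 1002 (502 up, 500 down), the last 632 without G1 3 and 643 without G1 1. With total reads as library size these were 692 (142 up, 550 down), 5088 (2 up, 5086 down) and 7238 (7224 up, 14 down), since the median gene then moved by -0.38, -1.25 and 1.75 log2, and by -0.09 in G2 against Late_S. With converted T positions they were 213 (168 up, 45 down), 428 (178 up, 250 down) and 752 (292 up, 460 down).

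The No_alkylation libraries were set beside the phases to see how far their steady-state levels stood from those of the alkylated libraries, since the labels do not say which cells they hold. They differed widely. Of 19 cholesterol synthesis genes 14 were lower in No_alkylation, 0 higher and 5 not called (14 adjusted over the list alone, median log2 -0.51), while of 18 homologous recombination genes 12 were higher and 6 not called (12 adjusted over the list alone, median 0.75). Ribosome biogenesis genes had 15 higher, 1 lower and 12 not called of 28 (20 and 1 adjusted over the list alone, median 0.27), splicing factors 17 higher, 6 lower and 5 not called of 28 (17 and 6, median 0.27), and oxidative phosphorylation genes 1 higher, 13 lower and 11 not called of 25 (1 and 13, median -0.25). CDC6 stood at 86.7 ± 15.1 CPM (SD, n = 3) in No_alkylation against a mean of 39.8 over the phases (adjusted p = 5.11e-11). MYC stood at 62.6 ± 1.37 against 36.7 (adjusted p = 2.91e-08). RRM2 stood at 285 ± 3.33 against 458 (adjusted p = 1.05e-13). CDKN1A stood at 164 ± 3.44 against 366 (adjusted p = 6.43e-15) and GAPDH at 5508 ± 69.4 against 8013 (adjusted p = 1.42e-17). In edgeR 6070 of 13972 genes passed, 3140 higher and 2930 lower. Against single phases the count was 4078 for G2, 4602 for Late_S, 5206 for G1 and 6109 for Early_S. Across genes, which are not independent replicates, the log2 difference went with the labelled share of the alkylated libraries (Spearman 0.266), with a median of -0.31 in the 10% of genes with the lowest share and 0.37 in the 10% with the highest.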

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

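Alternatives chosen only after the data had been seen were thinning to equal T>C totals, leaving out Early_S 2 with G2 2, and list tests after background subtraction. Of 413 recomputed counts, rates and list totals, 363 stayed within 1.5 times the reported count or on the same side of the threshold, and 50 moved, among them leave-outs of 1 library. The conversion rate and T>C read share differed across phases under every alternative run (exact permutation p of 0.00694 and 0.00521 within replicate numbers). Whether these pair libraries is unknown. The cause of the moves below was not tested unless stated.

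Steady-state genes in G2 against Late_S, 20 as reported, were 115 with DESeq2, 67 without a filter, 48 with the replicate number as a block, 49 with only both phases in the fit and 13 without Early_S 2 and G2 2. The 49 steady-state list calls became 32 with an estimated correlation. Nascent counts with DESeq2 were 1854 across phases, 748 in Late_S against Early_S and 103 in G2 against Late_S. That last count was 33 without a filter, 12 at 50 counts on average, 1 with only both phases in the fit and 17 without Early_S 2 and G2 2. Early_S against G1 gave 952 nascent genes with only both phases in the fit. Scaled by all reads, nascent counts were 6440 across phases, 4196 in Late_S against Early_S and 6198 in G1 against G2, since this scaling keeps the general change in labelling. With converted T positions they were 788 across phases, 353 in Early_S against G1 and 250 in Late_S against Early_S. Labelled share counts with total reads as library size were 7120, 5088 (Late_S against Early_S) and 7238 (G1 against G2), for the same reason, and 8 in G2 against Late_S. With converted T positions they were 998, 213 (Early_S against G1), 428 (Late_S against Early_S) and 1 (G2 against Late_S).

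Leaving out 1 library at a time gave steady-state counts of 2572 to 3455 (Early_S against G1), 947 to 1678 (Late_S against Early_S), 3 to 37 (G2 against Late_S), 2195 to 3005 (G1 against G2) and 3974 to 4618 across phases. Nascent counts were 358 to 682, 226 to 528, 1 to 19, 542 to 837 and 842 to 1329 in that order, and labelled share counts 408 to 693, 653 to 1046, 1 to 7, 632 to 997 and 1304 to 1744. List calls ranged from 44 to 51 (steady-state) and 32 to 37 (nascent), and, leaving out only No_alkylation libraries, genes labelled above background from 10266 to 10289 and genes that differ in No_alkylation from 5061 to 5219.

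For genes named singly, called steady-state values kept direction and call in 2888 cases and lost the call in 48, while those not called gained a call in 29. Nascent values did so in 1958 and 43 cases and labelled shares in 169 and 18. Of the cases that kept the call, 1580, 871 and 120 were fits without 1 library. Rule-named genes whose call ended in such fits had mostly been left out of the text, so these cases are no independent check. Direction reversed in 9 nascent cases. Scaled by all reads, the log2 changes in Late_S against Early_S became -0.24 for CCNF, -0.41 for KPNA2, -0.10 for KIF23, -0.22 for JUN and -0.20 for RPS29, and in G1 against G2 0.49 for HSP90AA1, 0.36 for COL1A1 and 0.25 for RPS29. With background subtracted RPS29 stood at 0.21 in G1 against G2. Of called lists, 58 of 85 kept the call with an estimated correlation, 82 of 85 with the replicate block and 31 of 36 nascent ones after background subtraction.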

Other observations

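The genes of the first paragraph and every test below were chosen only after the result was seen, except the test of spread in steady-state counts, which was set before.

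Some single genes of the matrix and cytoskeleton, picked from the data, were labelled most in Early_S, though of 19 genes of the fixed matrix list only 5 rose in labelled share from G1 to Early_S and 14 were not called. TIMP1 had a labelled share of 24.9% in Early_S against 3.80% in G1, 3.12% in Late_S and 2.99% in G2, while its steady-state level fell from 1025 ± 86.1 CPM (SD, n = 3) in G1 to 685 ± 28.3 in Early_S and 555 ± 34.0 in Late_S. COL1A1 had shares of 23.4%, 32.7%, 18.8% and 19.7% from G1 to G2, TAGLN 3.97%, 10.5%, 2.50% and 2.35%, and KRT8 9.29%, 15.9%, 5.11% and 6.77%. No explanation for these 4 genes was tested, and whether new RNA of these genes is soon lost again is not analysed here.

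The labelled read share was lower in Late_S and G2 than in G1 and Early_S. Fewer conversions per labelled molecule could lower converted positions per T>C read. The within-gene log2 ratio of these, Late_S over Early_S, was 0.05 over 5078 genes (0.0478512). The lowest Late_S library median (2.37) lay above the highest of Early_S (2.32). Over whole libraries the ratio of converted positions to T>C reads was 2.07 in G1, where the share was highest, against 2.38 in Late_S and 2.35 in G2. That ratio covers only reads already called T>C, and its columns may be filtered differently, since No_alkylation libraries had 0.828 converted positions per T>C read. A change in which genes make up the libraries would leave each gene's share alone, but the median within-gene log2 change was -0.94 (-0.938841) over 7475 genes, from -1.01 to -0.87 across pairs of libraries. A change of genes is excluded as the whole cause. Among reads called T>C, converted positions per read did not fall from Early_S to Late_S. Molecules with too few conversions to be called drop out of that ratio, so it cannot decide on fewer conversions per labelled molecule. More unlabelled RNA per cell, a lower rate of synthesis per existing RNA and differences in sorting or handling stay open and untested.

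T>C reads of ribosomal protein genes were higher in G2 than in G1 relative to other genes. Conversions without labelling were weighed by subtracting the No_alkylation share, after which the median log2 of G1 over G2 was -0.23 (-0.233268, quartiles -0.50 to -0.06) against -0.29 before over 83 genes, with the camera adjusted p still under 0.05. Subtraction left most of the shift (camera at the preset correlation only). RPS29, with 22.8% T>C reads in No_alkylation, turned from -0.99 to 0.21 and was not called. Scaled by all reads the median is 0.95, so only the relative change is described. A biological cause was not tested.

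Few genes differed between G2 and Late_S. A larger spread between replicates of these phases is excluded for steady-state counts, where the median SD of log2 CPM in Late_S and G2 was 0.995 (0.995023) times that in G1 and Early_S. For T>C reads the ratio was 1.43 (1.43257), with median SDs of 0.343 in G1, 0.410 in Early_S, 0.478 in Late_S and 0.572 in G2, between the bounds of 1.2 and 1.5 set for steady-state counts. For these reads a larger spread and a smaller difference cannot be told apart, though G1 against G2, with the same G2 libraries, gave 838 genes. The purity of the sort gates is not given in the sources used here and stays open.

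Other splits of the libraries into groups of the same sizes were fitted in the same way. For each result with enough splits, 1 split, the real one, gave as many calls. At most 100 splits were drawn, out of 15400 possible ones for the phases. The share of splits with as many calls could thus not fall below 0.01, or 0.025 with 40 splits. The splits bound chance no further than that, and for list calls other splits came near the real totals. Steady-state genes across phases were 4693 against at most 1217 in the other 99 of 100 splits, and list calls 49 against 39. Nascent genes were 1192 against 275 and list calls 36 against 31. The labelled share gave 1676 against 428 in 40 splits, No_alkylation against the phases 6070 against 291 in 60, and genes above background 10901 against 5977 in 40. For each of the 12 contrasts, 3 libraries against 3 give 10 splits, too few for a share under 0.05. The highest count of another split was 1 for steady-state genes in Late_S against Early_S (real 1547) and nascent genes in G2 against Late_S (real 6), and 0 for the other contrasts, whose real counts are those of the report.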
